A study of Mus musculus with 9 samples.

How the data were processed

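RNA from RSC96, a rat Schwann cell line, was sequenced in 9 libraries that fall into 3 groups of 3: control cells (SCs), cells treated with conditioned medium of menstrual blood-derived stem cells (MenSCs; M-SCs) and cells treated with exosomes of those stem cells (E-SCs). Per the labels' protocols, mRNA was enriched with oligo(dT) beads, cDNA was made with random hexamers, and libraries were sequenced paired-end on the Illumina HiSeq platform. Per the labels, the sample titles describe the control cells as cultured with control MenSCs, whereas the design text calls them control SCs. No label says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The submitters' processing notes name HISAT2, StringTie and the mouse build mm10, with no versions and no role for each. All 819 gene identifiers in the deposited tables were rat Ensembl identifiers, so the stated mouse build does not match the annotation of the tables, and no coordinates are given.

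The 3 tables analysed here hold 1 pair of groups each, with the 6 libraries of its pair. Per the values, each holds only genes that the authors had already selected, with p under 0.05 and at least a 2-fold difference. The listed genes as analysed here number 185 for E-SCs against SCs, 405 for M-SCs against SCs and 555 for E-SCs against M-SCs, or 819 together. The per-library log2 values deposited by the authors are, from the values, the log2 of a library-scaled read count plus 1. In each library all scaled counts up to 1000 reads were whole multiples of 1 step, within a tolerance of 0.01 reads, so that the reads behind a value could be read off. FPKM values deposited by the authors stand in 2 of the tables and are missing from that of E-SCs against SCs, and 81 of its 185 genes have no FPKM in any table used here. Each p-value and FDR is the authors' own, and their test is not given in the sources used here. The ratio of the authors' FDR to their p gave the number of genes they tested, 18409, 18503 and 18514 in the order above, from ratios that gave a whole rank for 82.2, 89.8 and 91.4% of the genes. By these ratios 5035, 6272 and 7430 genes had a p at or under the largest listed p. That is 27.4, 33.9 and 40.1% of the genes tested. The listed genes were 3.67, 6.46 and 7.47% of them, so most genes with such p-values were not listed.

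The design fixed before the data were examined assumed log2(FPKM + 1). Because 1 table lacks FPKM, the main test was limma 3.58.1 with a mean-variance trend, in R 4.3.3, on the authors' log2(scaled count + 1), fitted on the 6 libraries of each table without a filter, with Benjamini-Hochberg adjustment over the listed genes and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with few reads. Adjusted p-values were computed over genes already selected on the same libraries, so they are smaller than a test over all genes would give, and the number of calls does not estimate how many genes changed. Differences are always the first group named minus the second. Other summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots. Tested on simulated data with 819 genes and 200 of them changed, limma recovered all genes changed by 1 or 2 on the log2 scale at a mean scaled count of at least 32. Below that count it recovered 49.2, 42.9 and 50.0% of the genes changed by 1 for the comparisons in the order above. Over all counts and both sizes of change, 3.21, 1.89 and 4.17% of its calls were false. Every simulated gene had the same log2 SD of 0.068 between libraries plus Poisson counting noise, and none was selected. Listed genes can spread more, such as Il10 with a log2 SD of 0.68 in E-SCs. The simulated rates may therefore be better than those for the real genes.

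The library totals are unknown, since the tables hold only selected genes. The steps gave the libraries' relative depth, which ran from 0.868 to 1.16 times that of the first E-SCs library. Reads over the genes with a value ran from 266674 to 609452 per library. Intervals on reads are exact 95% binomial intervals and cover counting error only, since PCR copies are not independent molecules; 3 reads over a group is the floor where a group has none. Replicates of a group differed by more than sampling noise in every pair, with a chi-square of 5.91 to 16.6 per degree of freedom, so none was counted as a repeat of another.

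The rule for named genes, fixed before the data were examined, took Sox11, Il7 and Il22ra2 from the series title. It also took the 8 largest increases and 8 largest decreases per comparison. These had an adjusted p under 0.05, a mean FPKM of at least 1 in a group and no overlap between the groups. Their symbol was not a predicted name, for which rat name patterns were added later to those fixed. Up to 4 members per gene list were taken on that adjusted p and mean FPKM alone. Of the genes named by this rule, the text describes a part, and some results are not reported here. Genes named outside it are said to be chosen after their values were seen. The 26 gene lists were fixed at the same time. A list with at least 5 members in a table was tested for direction against the other genes of that table with a two-sided Fisher's exact test, which made 9 tests, none of them for E-SCs against SCs. Whether a list was over-represented among the listed genes was asked later, after the data were seen, with a one-sided Fisher's exact test against the number of genes the authors tested, over 78 tests. All members of a list were taken as tested, which understates an enrichment where some were not.

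Alternatives were other pseudocounts (0.1 and 0.01), a filter at a mean FPKM of at least 1, scaling to equal medians, the replicate number as a block, limma without a trend or with robust variances, all 9 libraries in 1 fit, and each library left out. Chosen after the data were seen were log2(FPKM + 1), a mean log2 value of at least 5, limma-voom on the whole reads, the removal of genes that were present in some and absent from other libraries of 1 group, and the authors' FDR. The comparisons of SCs with either treatment share the 3 control libraries. To ask what agreement this sharing alone could give, 1000 sets of unchanged groups against shared controls were simulated. No count model was used, since the tables hold no raw counts of all genes.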

Results

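Poly(A)-selected RNA of RSC96 Schwann cells was measured by RNA-seq in 3 control libraries (SCs), 3 libraries of cells given conditioned medium of menstrual blood-derived stem cells (M-SCs) and 3 of cells given exosomes of those stem cells (E-SCs). The study asked which genes linked to Schwann cell proliferation differed between the groups. Values are the authors' library-scaled read counts, given as mean ± SD over the 3 libraries of a group. Only genes that the authors had selected as differing at least 2-fold were analysed here, so a gene absent from a comparison was not shown to be unchanged in it.

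The comparison of E-SCs with SCs asked what differed after exosomes. If the sample titles hold, SCs were cultured with control MenSCs, so a difference from SCs need not be one from untreated cells. The 4 listed members of the immediate early list were lower in E-SCs. Of the same list, 3 other genes were listed for M-SCs against SCs, and all 3 were lower in M-SCs. None of the 4 genes lower in E-SCs was listed there. For E-SCs against M-SCs, 5 members were listed, 4 lower in E-SCs and 1 higher (Fisher's exact p = 0.41, adjusted p = 0.61). Fosb, a subunit of the AP-1 transcription factor, had a scaled count of 451 ± 23.4 (SD, n = 3) in E-SCs and 1263 ± 115 in SCs, a log2 difference of -1.48 (SE 0.10, limma adjusted p = 3.71e-05). Dusp1, a phosphatase that switches off MAP kinases, was at 2735 ± 148 in E-SCs and 5767 ± 199 in SCs (log2 difference -1.08). In M-SCs, Fosb was at 1160 ± 131 and Dusp1 at 7554 ± 119. Fos and Klf2, which lie outside the naming rule and were chosen after their values were seen, differed by -1.31 and -1.55. All 4 members of the 40-gene list that were listed for E-SCs against SCs passed limma's test, adjusted over the listed genes and over the list alone. Of all 185 listed genes 65.4% passed, having been selected on the same libraries. Hes1, a transcriptional repressor downstream of Notch, showed the largest decrease among the 9 genes the rule allowed. It fell from 769 ± 55.1 in SCs to 205 ± 16.0 in E-SCs, or -1.90 (SE 0.11). FPKM was known here only for genes also listed in another comparison, and for some in 1 group only. Genes without it could not meet the rule's FPKM limit.

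Other genes of this comparison went both ways. Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 411 ± 2.79 to 148 ± 26.9, a log2 difference of -1.48 (SE 0.16). Klra2, a lectin-like receptor gene, rose from 65.5 ± 21.3 to 186 ± 19.2, and Il10, an anti-inflammatory cytokine, rose from 37.2 ± 4.52 to 83.2 ± 37.0. The increase of Il10 was near the threshold (limma adjusted p = 0.040) and missed it without SCs replicate 1, 2 or 3 or E-SCs replicate 2 or 3 (adjusted p from 0.080 to 0.11). Of the interleukin and receptor list, 4 members were listed, Il7 and Il22ra2 of the series title among them, all of them higher in E-SCs, and 3 passed limma's test adjusted over the listed genes, against 4 adjusted over the list alone.

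**Figure D1:**
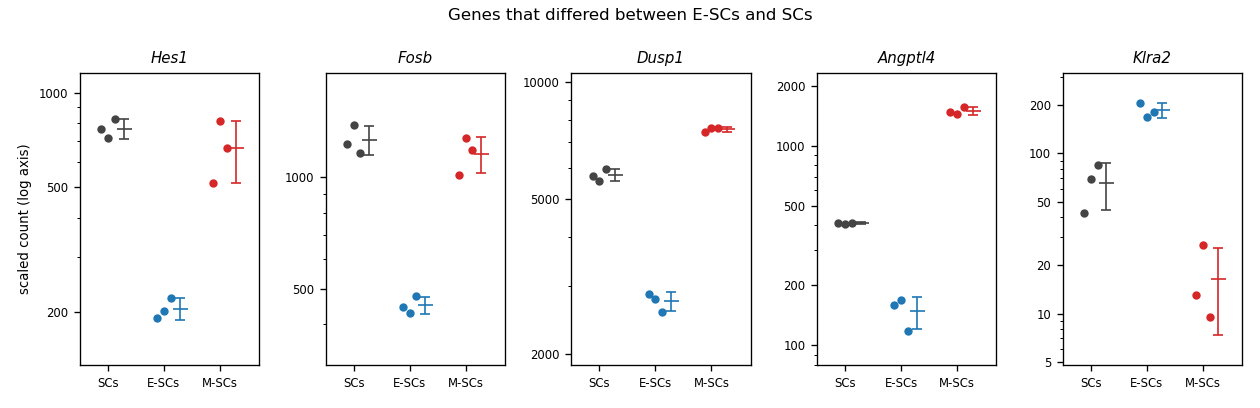
Scaled counts on a log axis for 5 genes in the 3 groups; each point is 1 library and the bar beside it is the mean ± SD of 3 libraries. Hes1, Fosb, Dusp1 and Angptl4 lie lower in E-SCs than in SCs and Klra2 lies higher.

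In total 121 of the 185 listed genes passed limma's test, 59 higher and 62 lower in E-SCs, and 85 of the 185 had an FDR under 0.05 in the authors' deposited table. Of the 185 listed genes, 79 had under 20 reads in their deepest library. The number past limma's test fell from 121 to 80, 78 and 80 without SCs replicate 1, 2 or 3. Without E-SCs replicate 1, 2 or 3 it was 105, 79 and 81. A fit with 1 library fewer also has less power.

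The comparison of M-SCs with SCs asked what differed after conditioned medium, with the same limit on what SCs were. Of the chemokine and NF-kB list, 10 of the 11 listed members were higher in M-SCs and 1 was lower. All 11 passed limma's test adjusted over the listed genes, as did 83.2% of all listed genes, and also adjusted over the list alone. Csf3, which encodes the granulocyte growth factor G-CSF, rose from 588 ± 48.7 to 3965 ± 211, a log2 difference of 2.75 (SE 0.08). Sod2, a mitochondrial superoxide dismutase, rose from 1641 ± 161 to 9228 ± 362, and Ccl2, a monocyte chemokine, from 1071 ± 60.4 to 3109 ± 161. Complement C3 had 2 reads over the 3 SCs libraries and 553 over the 3 M-SCs libraries, a ratio per depth of 275 with an exact 95% interval of 75.7 to 2275. Cd14, the only listed member of the macrophage and leukocyte marker list, rose from 201 ± 36.7 to 570 ± 59.5 (log2 difference 1.51, SE 0.14). Of the interleukin and receptor list, 3 listed members were higher in M-SCs and 3 lower (Fisher's exact p = 0.68, adjusted p = 0.70). The test of the chemokine and NF-kB list's direction against that of the other listed genes did not pass after adjustment (two-sided Fisher's exact test, p = 0.056, adjusted p = 0.17), and passed among genes with a mean FPKM of at least 1 (adjusted p = 0.049).

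Genes of the hypoxia and glycolysis list were higher in M-SCs in 5 of 5 listed cases. All 5 passed limma's test, as did 83.2% of all listed genes. Slc16a3, a lactate exporter, rose from 1333 ± 44.2 to 3259 ± 76.5 and Adm, the vasodilator adrenomedullin, from 180 ± 23.4 to 490 ± 57.9. The test of this list's direction did not pass (Fisher's exact p = 0.16, adjusted p = 0.29). Lower in M-SCs were Tnfsf18, a ligand of the TNF family, at 125 ± 13.0 against 727 ± 81.0, and Akap12, a kinase-anchoring protein, at 36852 ± 212 against 121420 ± 3578 (log2 difference -1.72, SE 0.03). Prx, the only listed member of the 26-gene myelination list, was also lower, at -1.29 (SE 0.11). The stress genes Gadd45a and Trib3 were lower too, at -1.22 and -1.32.

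In total 337 of the 405 listed genes passed limma's test, 204 higher and 133 lower, and 285 had an FDR under 0.05 in the authors' deposited table. With a filter at a mean FPKM of at least 1, 166 of 178 genes passed.

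The comparison of E-SCs with M-SCs set the 2 treatments against each other. The chemokine and NF-kB list was lower in E-SCs in 11 of 11 listed members. All 11 passed limma's test, as did 92.1% of all listed genes. The list's direction differed from that of the other genes (two-sided Fisher's exact test, p = 0.0035, adjusted p = 0.032). The direction tests take the genes of a list as independent, which they are not, so their p-values may be too small. Cxcl1, a neutrophil chemokine, had a scaled count of 3477 ± 99.4 in E-SCs and 15087 ± 935 in M-SCs, a log2 difference of -2.12 (SE 0.05). Csf3 differed by -3.05 (SE 0.06), Sod2 by -2.74 (SE 0.06) and Cd14 by -1.82 (SE 0.11). Of the hypoxia and glycolysis list, 8 of 9 listed members were lower in E-SCs (Fisher's exact p = 0.088, adjusted p = 0.20, and 0.049 at a mean FPKM of at least 1), among them Adm at -2.34 (SE 0.14) and Slc16a3 at -2.09 (SE 0.06), and Hif3a, chosen after its values were seen, was higher.

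Genes of the G1/S transition and DNA replication were lower in E-SCs than in M-SCs in 8 of 8 listed cases. All 8 passed limma's test adjusted over the listed genes, as did 92.1% of all listed genes, and also adjusted over the list alone. The test of this list's direction did not pass after adjustment (Fisher's exact p = 0.024, adjusted p = 0.11) but did at a mean FPKM of at least 1 (adjusted p = 0.049). E2f2, a cell cycle transcription factor, was at 171 ± 23.7 in E-SCs and 582 ± 27.7 in M-SCs. The replication licensing genes Cdc6 and Mcm3 differed by -1.29 (SE 0.07) and -1.17 (SE 0.04). None of the listed genes of either comparison with SCs belonged to this list, and no member of the G2/M list was listed in any of the 3 tables. Higher in E-SCs were Tnfsf18 at 3.43 (SE 0.09), Akap12 at 2.30 (SE 0.02), Gadd45a at 1.55 (SE 0.06) and Trib3 at 1.40 (SE 0.03).

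**Figure D2:**
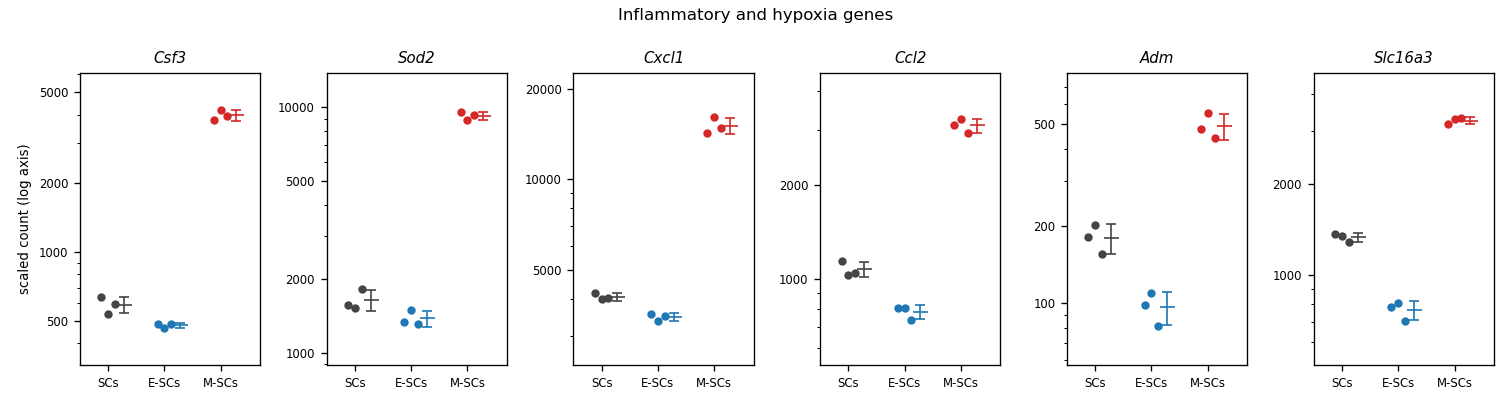
Scaled counts on a log axis for 4 inflammatory genes (Csf3, Sod2, Cxcl1, Ccl2) and 2 hypoxia genes (Adm, Slc16a3) in the 3 groups; points are libraries and bars the mean ± SD of 3. All M-SCs libraries lie above all libraries of the other groups.

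In total 511 of the 555 listed genes passed limma's test, 203 higher and 308 lower in E-SCs, and 441 had an FDR under 0.05 in the authors' deposited table. With a filter at a mean FPKM of at least 1, 270 of 282 genes passed.

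The genes of the series title were Sox11, a transcription factor of immature cells, Il7, a lymphocyte growth factor, and Il22ra2, a soluble receptor that binds IL-22. Sox11 had 27, 23 and 9 reads in the SCs libraries, 5, 6 and 3 in E-SCs and 3, 4 and 6 in M-SCs, and fell in both (-1.66, SE 0.51, limma adjusted p = 0.030 in E-SCs; -1.86, SE 0.53, adjusted p = 0.012 in M-SCs). Il7 had 0, 0 and 3 reads in SCs, 7, 9 and 8 in E-SCs and 4, 12 and 11 in M-SCs, and rose in both (2.55, adjusted p = 0.023; 2.47, adjusted p = 0.017). Il22ra2 had 7, 3 and 0 reads in SCs, 8, 8 and 18 in E-SCs and 3, 29 and 14 in M-SCs, and did not pass limma's test in either (2.01, SE 0.84, adjusted p = 0.063; 1.96, SE 0.97, adjusted p = 0.079). In the authors' deposited table the FDR was 0.032 and 0.0096 for Sox11, 0.078 and 0.058 for Il7, and 0.13 and 0.0499 for Il22ra2, in E-SCs and M-SCs in turn. In E-SCs the call for Sox11 was lost without SCs replicate 1 (adjusted p = 0.093), SCs replicate 2 (0.082), E-SCs replicate 2 (0.053) or E-SCs replicate 3 (0.079). That for Il7 was lost without the same libraries (adjusted p from 0.061 to 0.074), and in M-SCs it was lost without SCs replicate 1, SCs replicate 2 or M-SCs replicate 2 (0.054 to 0.063).

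**Figure D3:**
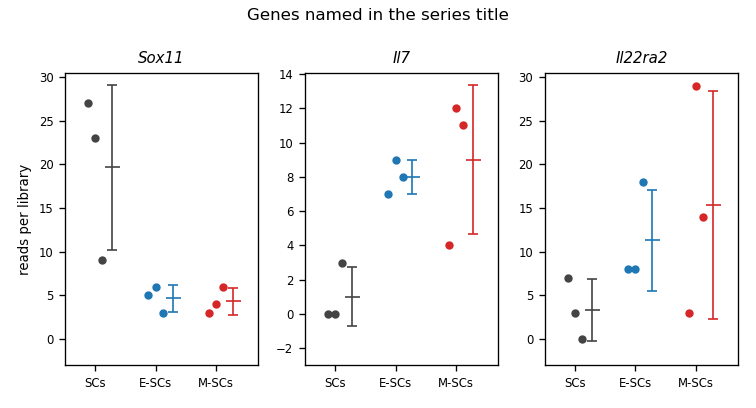
Reads per library for the 3 genes of the series title; points are libraries and bars the mean ± SD of 3 libraries. No library holds over 29 reads for any of them.

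Both treatments were compared with the same control libraries. Of 39 genes listed in both comparisons, 29 went the same way, 19 higher and 10 lower. Independent lists of these sizes would share 1.34 higher and 0.73 lower genes among 18409, and opposite directions would hold 0.86 genes higher in E-SCs and 1.14 lower, against 4 and 6 observed. Unchanged groups set against shared controls put a mean of 2.09 genes per simulated set in both lists, against the 39 observed. Of those simulated genes 98.5% went the same way, against 74.4% of the observed ones. With so few simulated genes the percentages cannot be compared, and no conclusion is drawn from them. The covariance of the log2 differences over the 39 genes was 2.60, against 0.53 in the simulation. The correlation across these genes, which are not independent replicates, was 0.59 against 0.47. For the covariance and correlation, the simulated differences were not selected for size as the observed ones were, so these values are not like for like. Because the genes were selected in both comparisons and 3 controls cannot be split, how much of the agreement comes from the shared controls cannot be told. Of the 29 genes, 5 were present in some and absent from other libraries of 1 group, and 12 of the 22 genes past limma's test in both comparisons went the same way.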

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

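The tests of explanations in this part were chosen after the results were seen. The 10 genes listed in all 3 comparisons moved in opposite directions in E-SCs and M-SCs against the same SCs, and the difference between the treatments was tested with limma. With E-SCs minus M-SCs on the log2 scale, it was -4.05 for LOC681458, -3.39 for Angpt1, -3.35 for Angptl4, -3.27 for Stc1, -3.08 for Prdm1 and -2.17 for AABR07006310.1, which were lower in E-SCs and higher in M-SCs than in SCs. It was 2.34 for Il10, 3.54 for Klra2, 4.03 for AABR07025051.3 and 4.11 for Piezo2, which went the other way. All 10 had a limma adjusted p of at most 9.38e-04 over the 555 genes of that table. A gene that moves 2-fold in opposite directions necessarily differs at least 4-fold between the treatments, so the presence of all 10 in the third table follows from how they were found. Piezo2 rests on 46 reads in E-SCs, 0 in M-SCs and 19 in SCs.

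The wider pattern is that of the 222 genes listed both for M-SCs against SCs and for E-SCs against M-SCs, 145 (65.3%) had E-SCs and M-SCs on opposite sides of SCs. The requirement of a 2-fold difference between the treatments favours such genes. Among the 154 genes that would have met it with either sign of E-SCs minus SCs, 77 (50%) lay on opposite sides. With 1 library left out, the share of these genes was 45.5 to 55.8%. Of the 15 among them called in E-SCs against SCs, 12 were on opposite sides (exact binomial p = 0.035, adjusted p over 4 tests = 0.070), and the percent was 60.0 at a mean log2 value of at least 6 (adjusted p = 0.21) and 73.5 at 8 or more (25 of 34 genes, adjusted p = 0.036; 70.6 to 76.5 with 1 library left out). With a common offset of the E-SCs libraries taken off, the percent was 49.4 over all 154 genes and 70.6 at 8 or more, where a fair coin stays at or under 67.6. Selection and an offset therefore cannot be told apart from opposite responses of abundant genes, since the levels were chosen after looking, the genes are not independent and low genes dilute the whole.

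For the counts of genes called, the 6 libraries of a comparison allow 10 splits, too few for a share under 0.05. The real split called 121, 337 and 511 genes for E-SCs against SCs, M-SCs against SCs and E-SCs against M-SCs, the highest other split called 1, 1 and 0, and in each comparison 1 of the 10 splits, the real one, gave as many. The genes had also been selected on these same groups, which lowers the count of every other split.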

How the results depend on the processing

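The log2(FPKM + 1) fit, the mean log2 filter, voom, the removal of genes present in only some libraries of a group, and the authors' FDR were chosen after seeing the data. Genes called for E-SCs against SCs (121) numbered 48 of 49 at a mean log2 value of at least 5, 80 of 104 in 1 fit of all 9 libraries, and 78 to 105 when 1 library was left out. For M-SCs against SCs (337) they numbered 166 of 178 at a mean FPKM of at least 1, 212 of 214 at a mean log2 of at least 5 and 222 of 251 with all 9 libraries, and for E-SCs against M-SCs (511) 270 of 282, 327 of 327 and 261 of 287. These filters and the 9-library fit test fewer genes. All other settings stayed within 1.5 times: 83 to 125, 275 to 355 and 429 to 521 genes, apart from the left-out libraries of the first comparison. With log2(FPKM + 1), 304 and 469 genes were called in the 2 tables that hold FPKM. Scaling to equal medians shifted the differences by -0.10, -0.31 and 0.34 and turned the split of higher and lower calls to 54 and 65, 168 and 153, and 225 and 256; the medians were those of genes selected for differing. The direction of the chemokine and NF-kB list in M-SCs against SCs, and of the G1/S and hypoxia lists in E-SCs against M-SCs, passed only at a mean FPKM of at least 1 (adjusted p = 0.049 for each); fewer genes and lists were then tested. Same-direction genes (29 of 39) numbered 8 of 17 at a mean FPKM of at least 1. They numbered 12 of 22 with limma calls in both comparisons, so their share fell in either case. Named genes were refitted only with a pseudocount of 0.1, equal medians, the block and each of 6 libraries left out. Of these 1026 alternatives for 114 named results, 989 stayed on their side of the threshold, 37 lost the call, over 9 results, and none reversed; 35 of the 37 left out a library, and the others were S100a8 at a pseudocount of 0.1 and Lsmem2 with the block.

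With the replicate number as a block, limma called 122, 338 and 493 genes. Same-numbered libraries did not deviate together: correlations were -0.10, -0.04 and 0.06 for E-SCs against SCs, -0.18, -0.07 and 0.12 for M-SCs against SCs, and -0.04, -0.05 and -0.04 for E-SCs against M-SCs, and not every library correlated best with its own number. The FPKM filter for E-SCs against SCs was not run, as 81 of its genes have no FPKM, nor were the tests on raw counts of all genes, which were not analysed here. Depth limits the low genes: those under 20 reads in their deepest library had an authors' FDR under 0.05 in 19.0, 33.0 and 43.6% of cases, against 66.0, 82.6 and 88.3% of the others.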

Other observations

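The tests in this part were chosen after the data were seen. Beyond the genes listed for both treatments, genes of the inflammatory and hypoxia lists could be followed in E-SCs through the 316 genes with values in all 9 libraries. Of 9 chemokine and NF-kB genes that were higher in M-SCs and listed in both M-SCs comparisons, 6 lay below SCs in E-SCs and 3 above. Of the 9, 4 were called lower in E-SCs than in SCs in a limma fit of the 9 libraries (Cxcl1 at -0.22, Ccl2 at -0.45, Csf3 at -0.30 and Sod2 at -0.24), and none was called higher. Of 5 hypoxia genes, all lay below SCs in E-SCs and 3 were called lower (Slc16a3 at -0.80, Adm at -0.89 and Egln3 at -0.96), and none was called higher. These differences were smaller than those of M-SCs, and the genes were picked by their difference between the treatments, which favours E-SCs values below SCs.

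Among the genes the authors tested, the chemokine and NF-kB list was over-represented in the table of M-SCs against SCs (11 of 40 members listed, 27.5% against 2.19% of all genes tested, one-sided Fisher's exact adjusted p = 4.92e-08) and in that of E-SCs against M-SCs (adjusted p = 6.52e-07). The hypoxia list (9 of 43, adjusted p = 1.08e-04) and the G1/S list (8 of 42, adjusted p = 5.81e-04) were over-represented in the latter, and the immediate early list (4 of 40, adjusted p = 0.011) in that of E-SCs against SCs. In all 12 of the 78 tests passed, among them less strongly the hypoxia list in M-SCs against SCs (adjusted p = 0.027) and in E-SCs against M-SCs the TGF-beta and YAP list (0.017) and the immediate early list (0.043). The 12 include the interleukin list in both comparisons with SCs, which shows nothing, since its listed members hold Il7 and Il22ra2 of the series title. Genes of a list are not independent of each other.

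Of the listed genes, 13 were present in some libraries of a group and all but absent from others, with at least 40 reads in 1 library and at most 2 in another of the same group. Cask had 266, 0 and 215 reads in E-SCs, 0, 207 and 0 in M-SCs and none in SCs, and Faim had 310, 0 and 273 in SCs, 260, 0 and 0 in E-SCs and none in M-SCs. Counting noise is excluded. At the mean read count most favourable to it, Poisson counts would put at most 1.05e-04 genes in total, among 18514 tested, past this rule. Over the 10 genes with several libraries above 40 reads the median SD of their log2 values was 0.187, as the assignment of reads to 1 of several like gene models may give, although LOC100911727 had 1239 and 344 reads; that explanation was not tested on sequence. Treatment was not tested, because the genes were picked for differing within a group; limma called 0, 3 and 0 of those listed in the 3 tables, whereas 3, 7 and 7 had an authors' FDR under 0.05.

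For the genes of the series title, an exact binomial test of the pooled reads in E-SCs against SCs gave p = 7.74e-07 for Sox11, 1.70e-05 for Il7 and 1.05e-04 for Il22ra2. The genes had been selected from 18409 on these libraries, and that many tests would give 0.0143, 0.312 and 1.93 genes at such p-values by counting noise alone. In E-SCs this argues against counting noise for Sox11 and leaves it open for Il7 and Il22ra2. In M-SCs the exact binomial test gave p = 2.12e-08, 8.45e-06 and 1.25e-06, or 3.92e-04, 0.156 and 0.0232 genes among 18503, which argues against counting noise for Sox11 and Il22ra2 and leaves it open for Il7. The test leaves out the spread between libraries. Whether exosomes differ from conditioned medium in these genes cannot be told apart from no difference. E-SCs minus M-SCs was 0.20, 0.08 and 0.04 in the limma fit of 9 libraries, and the 95% limits reached 2.08 from 0, so the changes of the 3 genes were not shown to belong to exosomes rather than to conditioned medium. Proliferation itself was not measured in these tables.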
